A study of Homo sapiens with 6 samples.

How the data were processed

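The series measured total RNA from AN3-CA cells, a human endometrial cancer line, on Affymetrix expression arrays. Per the labels' protocols, cells were cultured for 24 h and then kept in serum-free medium for 18 h with DMSO alone, with DMSO and 10 ng/mL acidic fibroblast growth factor (aFGF, also FGF1), or with 300 nM AZD4547 and the same dose of aFGF. AZD4547 is an inhibitor of the FGF receptor tyrosine kinases. RNA was extracted with TRIzol, and biotin-labelled cRNA was prepared from 500 ng of total RNA. Each of the 3 groups holds 2 samples that the labels call biological replicates, so 6 arrays entered the fits. The labels give the vehicle concentration as 0.5% DMSO and do not say how much DMSO the AZD4547 cultures received. There was no group with AZD4547 and no aFGF.

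The submitters' processing notes name RMA, which corrects the background, normalizes arrays by quantiles and summarises probes, with no version. The deposited intensity values were on a linear scale, from 0.75 to 6344.2 with array medians between 7.176 and 7.428, where log2 values had been assumed before the data were examined. The array type and the step that returned RMA values to a linear scale are not given in the sources used here. The log2 of each intensity was taken, with no pseudocount, and every fold change below is a difference of mean log2 intensities. Sorted log2 values had a median range of 0.053 across the 6 arrays. The authors' deposited table also holds, per probe set, a ratio of each aFGF group over the DMSO group, which equals the ratio of the mean linear intensities, and a p-value whose test is not given in the sources used here. The values per sample were identical in both deposited tables (largest difference 0), so exchanging them changed nothing.

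Of 49293 probe sets, 47340 carried 1 gene symbol, 1457 carried several and 496 carried none. Symbols were brought up to date through Entrez identifiers, which matched a RefSeq gene table for 47089 of the probe sets with 1 symbol and changed 5313 symbols. Each of 19040 genes was represented by its single-symbol probe set with the highest mean over the 6 arrays. Of these genes, 12320 had more than 1 probe set and 2234 were represented by one ending in _x_at, the suffix for probes that can match other transcripts. The table holds no detection calls, and no filter on dim genes was applied in the fits reported first. The number of arrays limits the precision. With 2 per group, the median standard error of a log2 fold change was 0.117.

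Group means were fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance (eBayes with trend), and 3 differences were tested: aFGF over DMSO, AZD4547 with aFGF over aFGF, and AZD4547 with aFGF over DMSO. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. All p-values of genes are limma's, two-sided. Gene lists were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation, adjusted over the 17 lists. With an estimate, camera also refers its statistic to the few residual degrees of freedom of the fit. Its p-values then grow even at a correlation near the preset one. The lists covered ERK pathway output, immediate early genes, FGF receptors with ligands and adaptors, other receptor tyrosine kinases, G1/S and replication, G2/M and mitosis, CDK inhibitors and quiescence, the BCL2 family, cholesterol synthesis, glycolysis, ribosome biogenesis and MYC targets, ATF4 and the unfolded protein response, interferon response, cytokines, epithelial, mesenchymal and matrix genes, lysosome and autophagy, and endometrial lineage. Marker lists of fibroblasts, endothelium, leukocytes and smooth muscle formed a separate family of 4. PTTG1 and SLC2A3, members of the lists, had no single-symbol probe set.

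The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, up to 4 called members of each list with the largest changes (or the largest change as a value where none was called), and FGFR1 to FGFR4. Some genes that the rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen. Gene Ontology terms, array weights and the removal of _x_at probe sets were added after the data were seen.

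The fits were tested on simulated arrays for the same 19040 genes. Over 10 draws with 200 changed genes in the aFGF comparison, 45.8% of changes of 0.5 on the log2 scale were called, 96.8% of changes of 1 and 100% of changes of 2 and 3, and 0.05% of unchanged genes were called. In the AZD4547 comparison the shares were 45.4%, 97.6%, 100% and 100%, with 0.05% of unchanged genes called. With changes placed in the AZD4547 arrays, the comparison with DMSO gave 48.8%, 97%, 100% and 100%, with 0.04% of unchanged genes called. The list test for aFGF found the shifted list in 10 of 10 draws and called 0 unshifted lists. In all these draws genes were independent, with variances from the fitted prior and the same spread in every group. Low rates of false calls were thereby built in and are not shown for the real arrays. In the gene tests only 200 genes were changed per draw, while the real comparisons called 892 to 4894. The adjusted threshold was therefore stricter in the draws, and the shares of changes called are not estimates for the real arrays. Simulated arrays with no effect, 100 draws, gave the values expected where comparisons share arrays.

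Alternatives were a replicate block, no intensity trend, a robust prior, dim genes left out (below the 40th percentile), renewed quantile normalization, centring on array medians, the mean of a gene's probe sets, every probe set, only the groups compared, a fold minimum, an estimated correlation or fry for the lists, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 in Python 3.11.15.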

Results

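Expression was profiled in AN3-CA endometrial cancer cells on 6 arrays, 2 cultures in each of 3 groups: DMSO, aFGF (10 ng/mL), and aFGF with the FGF receptor inhibitor AZD4547 (300 nM), each for 18 h in serum-free medium. Cultures of 1 group correlated at r = 0.9966 across probe sets in DMSO, 0.9973 with aFGF and 0.9973 with AZD4547. Genes are not independent replicates, so these values describe the arrays only. The DMSO cultures differed most from each other, with an SD of log2 differences of 0.181 in the brighter probe sets against 0.122 with aFGF and 0.135 with AZD4547. Principal components were taken over the brighter probe sets only. The first held 74.5% of their variance and set aFGF (loadings 0.55 and 0.56) apart from AZD4547 with aFGF (-0.42 and -0.42), with DMSO between them (-0.15 and -0.11). The second held 11.7% and had its highest loading, 0.83, in DMSO replicate 1.

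The first comparison asked which transcripts aFGF altered. The largest rise was that of EMP1, an epithelial membrane protein, from a mean log2 intensity of 4.18 ± 0.03 (SD, n = 2) in DMSO to 8.59 ± 0.05 (SD, n = 2) with aFGF. This is a 21.2-fold change (log2 4.41, SE 0.09, limma adjusted p = 1.1e-10). VGF, a secreted neuropeptide precursor, rose 16.7-fold. PHLDA1 rose 11.6-fold, the transcription factor EGR1 8.76-fold, the cytokine LIF 7.71-fold and the carboxypeptidase CPA4 7.30-fold. S100A2 rose as well (log2 2.64). Falls were smaller. The methyltransferase gene TMT1A (METTL7A in the deposited annotation) was 4.31-fold lower (log2 -2.11, SE 0.05, adjusted p = 5.4e-10), followed by the zinc finger gene ZNF480 (log2 -1.82), NREP (-1.59), ANKEF1 (-1.55), the arginase ARG2 (-1.44), the interferon-induced IFIT1 (-1.42), TENT5B (-1.36) and the GABA transaminase ABAT (-1.36). S100A2 stood at 2.78 in DMSO and ANKEF1, TENT5B and ABAT at 1.77, 1.59 and 1.08 with aFGF (ABAT also at 2.43 in DMSO), below the array medians of log2 intensity (2.843 to 2.893). With no detection calls, such levels are not shown to be above background, and the sizes of these changes are uncertain.

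Immediate early genes, which growth factors switch on without new protein synthesis, rose together with aFGF. Of 20 measured, 11 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 4.1e-12). With an estimated correlation the adjusted p = 0.046. EGR2 (log2 2.31, SE 0.18), JUN (1.94, SE 0.11) and CCN1 (1.84, SE 0.09) followed EGR1 in this list. EGR2 started from a mean log2 intensity of 1.01, below the array medians, so the size of its rise is uncertain. Ribosome biogenesis and MYC target genes rose with aFGF in 24 of 34 cases and fell in 0 (27 and 0 adjusted over the list alone, median log2 0.33, camera adjusted p = 1.7e-18, adjusted p = 0.031 with an estimated correlation). MYC, the transcription factor, rose by 0.92 (SE 0.08), UTP20 by 0.60 (SE 0.08), and RRP12 and GAR1, which act in ribosomal RNA processing, by 0.54 (SE 0.08) and 0.53 (SE 0.06).

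ERK pathway output and feedback genes moved both ways with aFGF. Of 24 measured, 10 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 4.7e-05, adjusted p = 0.071 with an estimated correlation). The stress gene IER3 rose by 1.49 (SE 0.05) beside PHLDA1, EGR1 and LIF. The members that fell, named after their values were seen, were the ETS factor ETV1 (log2 -1.23, SE 0.07) and the receptor signalling antagonists SPRY2 (-0.37, SE 0.05) and IL17RD (-0.28, SE 0.06). DUSP6, a phosphatase of ERK, had a log2 fold change of 0.06 (SE 0.06, adjusted p = 0.64).

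Cell division genes were lower with aFGF. In the G2/M and mitosis list 19 of 33 measured genes fell and 0 rose (24 and 0 adjusted over the list alone, median log2 -0.24, camera adjusted p = 2.8e-12, adjusted p = 0.046 with an estimated correlation). The kinesin KIF20A had a log2 fold change of -0.68 (SE 0.07), the kinetochore protein CENPF -0.54 (SE 0.06) and the topoisomerase TOP2A -0.52 (SE 0.06). In the G1/S and replication list 9 of 38 fell and 0 rose (14 and 0 adjusted over the list alone, camera adjusted p = 4.7e-05, adjusted p = 0.077 with an estimated correlation), with TK1 (-0.41, SE 0.06) and the helicase subunit MCM3 (-0.38, SE 0.05) among them. CDK inhibitors and quiescence genes fell in 10 and rose in 4 of 28 cases (12 and 5 adjusted over the list alone, camera adjusted p = 0.031, adjusted p = 0.18 with an estimated correlation). CCNG2 (log2 -0.84, SE 0.08) and the inhibitors CDKN2C (-0.69, SE 0.06) and CDKN1B (-0.64, SE 0.10) fell, while CDKN1A, also an inhibitor of CDKs, rose by 0.93 (SE 0.18) from a dim level of 2.86. The CDKN1A call was lost without aFGF replicate 1. The list call was lost without DMSO replicate 1, DMSO replicate 2 or aFGF replicate 2, with adjusted p up to 0.12, and without dim genes (0.18).

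Cholesterol synthesis genes fell in 8 and rose in 3 of 24 cases (9 and 4 adjusted over the list alone, camera adjusted p = 0.045, adjusted p = 0.23 with an estimated correlation), with LSS at -0.72 (SE 0.08) and STARD4, a sterol carrier, up by 0.78 (SE 0.07). Interferon response genes fell in 8 and rose in 2 of 30 cases (9 and 2 adjusted over the list alone, camera adjusted p = 0.049, adjusted p = 0.33 with an estimated correlation), with ISG15 at -0.87 (SE 0.07) and the transcription factor IRF1 up by 0.59 (SE 0.08). The cholesterol call was lost without DMSO replicate 2 or aFGF replicate 1 (adjusted p up to 0.11), without dim genes (0.21), after median centring (0.051) and without _x_at probe sets (0.063). The interferon call was lost without any array except aFGF replicate 1 (adjusted p up to 0.12) and without _x_at probe sets (0.099).

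Transcripts of the FGF receptors behaved differently from one another. FGFR2 was 2.27-fold lower with aFGF (log2 -1.18, SE 0.05, adjusted p = 1.2e-07). FGFR4 rose by 0.30 (SE 0.08, adjusted p = 0.025), a call lost without any array except DMSO replicate 2. FGFR1 had a log2 fold change of -0.10 (SE 0.05, adjusted p = 0.19) and FGFR3 of 0.02 (SE 0.08, adjusted p = 0.92). The list of FGF receptors, ligands and adaptors had 6 rises and 3 falls among 20 genes (6 and 3 adjusted over the list alone) and no shift (camera adjusted p = 0.57). Among other receptor tyrosine kinases, where MERTK rose by 0.78 (SE 0.08), 1 gene rose and 3 fell of 22 (1 and 3 adjusted over the list alone, camera adjusted p = 0.99).

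In all, aFGF changed 2979 of 19040 genes, 1128 upward and 1851 downward, against 5055 genes at an unadjusted p under 0.05. The median size of a called change was 0.39 on the log2 scale, and 69 genes rose and 32 fell at least 2-fold. Without aFGF replicate 1 or 2 the count was 1239 or 1147, the remaining aFGF culture being assumed to vary like the other groups, and without the intensity trend it was 1489. In the authors' deposited table, 6798 of 49293 probe sets had a p under 0.05 for aFGF over DMSO, 3158 with a ratio above 1 and 3640 below. These are probe sets at a p with no stated adjustment, so their number is not comparable with the genes called here.

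**Figure D1:**
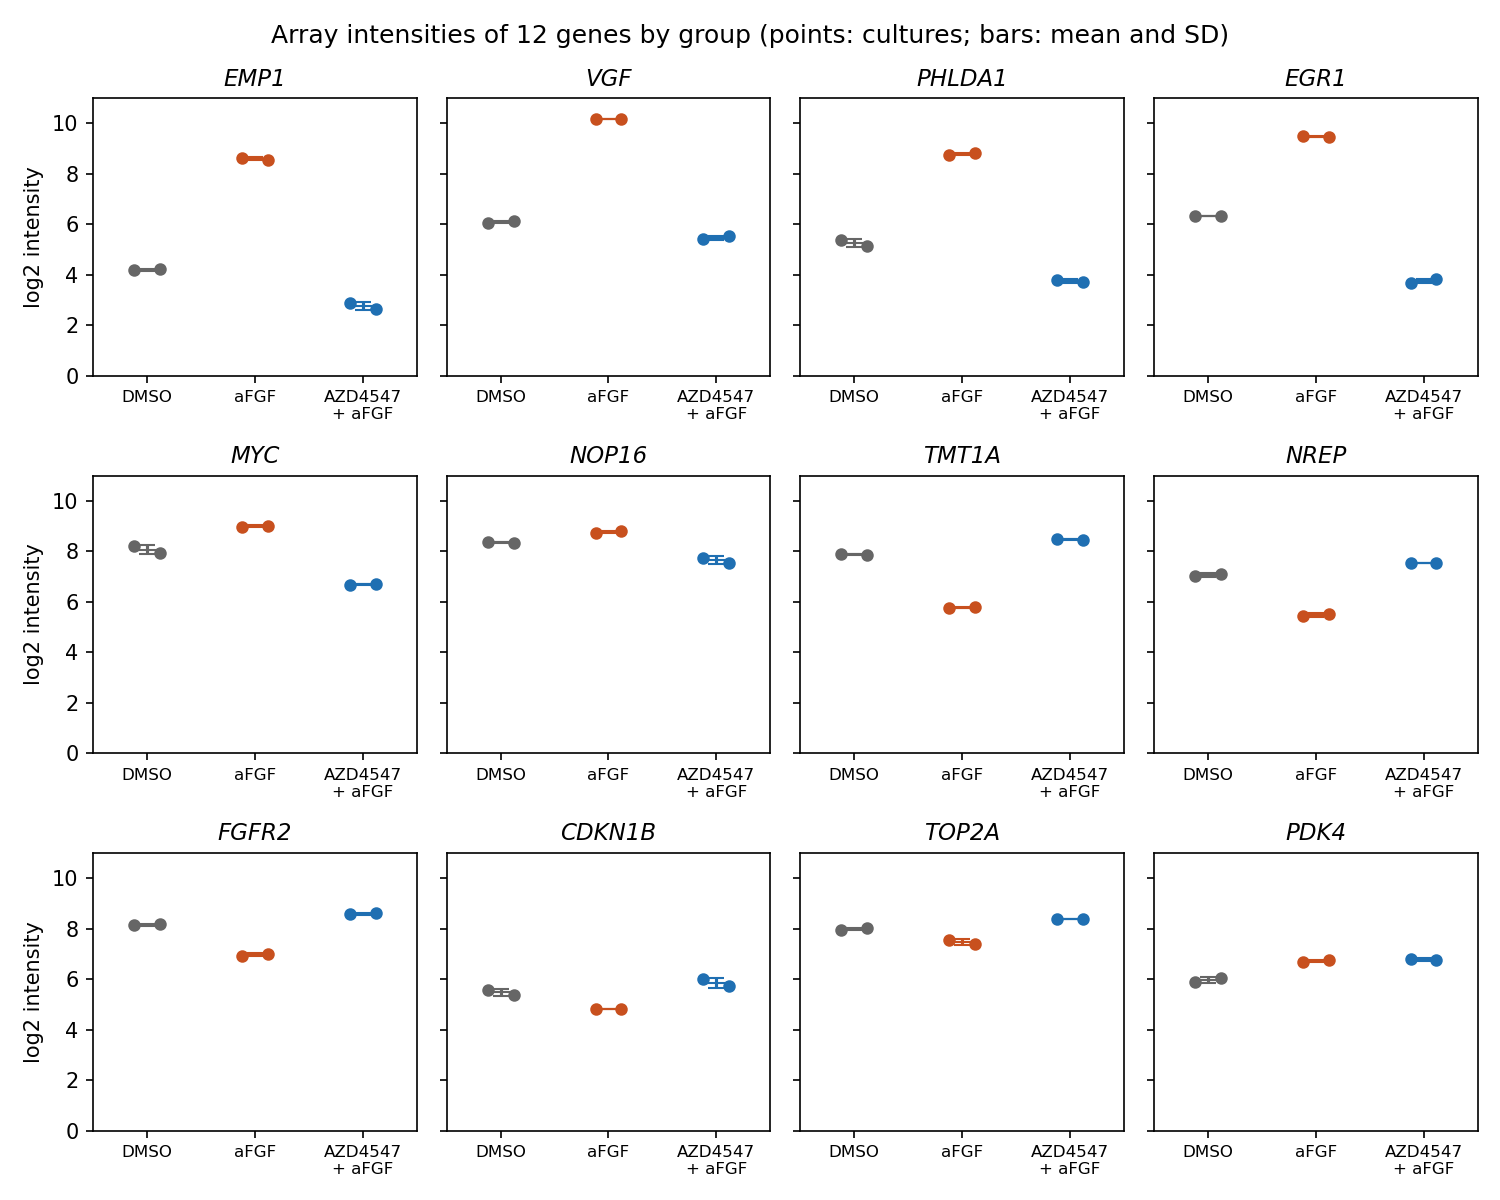
Log2 array intensity (vertical axis) of 12 genes in the DMSO, aFGF and AZD4547 with aFGF groups, with a point per culture and bars for the mean and SD of 2 cultures. EMP1 stood at 4.18, 8.59 and 2.75 in these groups and TMT1A at 7.87, 5.76 and 8.47, while PDK4 stood at 5.98, 6.73 and 6.78.

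The second comparison asked what AZD4547 altered in cells given aFGF. The genes that led the response to aFGF led here with the opposite sign. EGR1 was 52.7-fold lower with AZD4547 (log2 -5.72, SE 0.06, limma adjusted p = 3.8e-13), PHLDA1 32.8-fold and VGF 25.9-fold. LIF was 13.9-fold lower and the stress-induced cytokine GDF15 12.6-fold. EMP1 (log2 -5.84, SE 0.09, adjusted p = 3.4e-12) and CPA4 (-3.13) fell to 2.75 and 2.86, at or below the array medians, so the sizes of these falls are uncertain. The largest rises were those of TMT1A (6.53-fold, log2 2.71, SE 0.05), ABAT (2.10, SE 0.16), NREP (2.08, SE 0.06), the plasma membrane calcium pump ATP2B4 (1.97, SE 0.11), IFIT1 (1.97, SE 0.09), the glycogen-targeting subunit PPP1R3C (1.90, SE 0.12), ARID5B (1.83, SE 0.11) and ZNF480 (1.79, SE 0.09). Of these, ABAT, PPP1R3C and ARID5B rose from dim levels with aFGF (1.08, 2.52 and 2.69).

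Ribosome biogenesis and MYC target genes fell almost throughout. Of 34 measured, 33 fell and 0 rose with AZD4547 (33 and 0 adjusted over the list alone, median log2 -0.70, camera adjusted p = 1e-28, adjusted p = 0.016 with an estimated correlation). MYC had a log2 fold change of -2.30 (SE 0.08), the nucleolar protein NOP16 -1.13 (SE 0.07), WDR74 -1.07 (SE 0.07) and the RNA polymerase I subunit POLR1B -1.05 (SE 0.06). Immediate early genes fell in 11 of 20 cases and rose in 0 (12 and 0 adjusted over the list alone, camera adjusted p = 2.2e-10, adjusted p = 0.043 with an estimated correlation). Examples were KLF10 (-2.18, SE 0.09) and JUN (-2.07, SE 0.11). EGR2 fell as well, to a level of 0.49, below the array medians, so the size of its fall is uncertain. ERK pathway output genes fell in 13 and rose in 4 of 24 cases (14 and 4 adjusted over the list alone, camera adjusted p = 2e-07, adjusted p = 0.043 with an estimated correlation). ETV1 rose by 1.79 (SE 0.07), IL17RD by 0.57 (SE 0.06) and SPRY2 by 0.42 (SE 0.05), against the direction of this list, while DUSP6 had a log2 fold change of -0.41 (SE 0.06, adjusted p = 0.00031). Among members not called were CCND1 at -0.16 (SE 0.12) and SPRY1 at -0.05 (SE 0.05). These genes, unlike EGR2, KLF10 and JUN, were named after their values were seen.

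Cell division genes rose with AZD4547. In the G2/M and mitosis list 29 of 33 rose and 0 fell (31 and 0 adjusted over the list alone, median log2 0.42, camera adjusted p = 7.4e-18, adjusted p = 0.040 with an estimated correlation), with TOP2A at 0.91 (SE 0.06), KIF20A at 0.90 (SE 0.07) and the phosphatase CDC25C at 0.74 (SE 0.08). In the G1/S and replication list 17 of 38 rose and 1 fell (20 and 1 adjusted over the list alone, camera adjusted p = 3.5e-06, adjusted p = 0.055 with an estimated correlation), with TK1 at 0.61 (SE 0.06) and RFC4, a subunit of the clamp loader, at 0.54 (SE 0.05). CDK inhibitors and quiescence genes rose at the same time, 14 of 28 with 3 falls (17 and 3 adjusted over the list alone, camera adjusted p = 0.00014, adjusted p = 0.055 with an estimated correlation). CCNG2 rose by 1.57 (SE 0.08), the antiproliferative gene BTG2 by 1.14 (SE 0.09), CDKN1B by 1.03 (SE 0.10) and CDKN2C by 1.01 (SE 0.06).

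The cholesterol synthesis, glycolysis and interferon lists were shifted upward with AZD4547 at the preset correlation but not with an estimated one. The G1/S and CDK inhibitor lists above shared this limit. The fry test also called the cholesterol synthesis, glycolysis and interferon lists upward (fry adjusted p = 0.0013, 0.0034 and 0.0041). Cholesterol synthesis genes rose in 14 and fell in 2 of 24 cases (15 and 3 adjusted over the list alone, camera adjusted p = 0.00036, adjusted p = 0.075 with an estimated correlation), with LSS at 1.08 (SE 0.08) and EBP at 0.63 (SE 0.06). Glycolysis genes rose in 9 and fell in 1 of 20 cases (11 and 2 adjusted over the list alone, camera adjusted p = 0.0078, adjusted p = 0.11 with an estimated correlation), with PFKFB4 at 1.44 (SE 0.09) and ALDOC at 0.85 (SE 0.06). With aFGF alone 6 glycolysis genes had fallen and 1 had risen (6 and 2 adjusted over the list alone), without a list call (adjusted p = 0.17, but 0.036 without DMSO replicate 1). Interferon response genes rose in 11 and fell in 2 of 30 cases (11 and 2 adjusted over the list alone, camera adjusted p = 0.0067, adjusted p = 0.20 with an estimated correlation), with ISG15 at 0.98 (SE 0.07), STAT2 at 0.87 (SE 0.08) and OAS3 at 0.86 (SE 0.09). FGFR2 rose by 1.63 (SE 0.05, 3.09-fold). FGFR4 had a log2 fold change of -0.40 (SE 0.08, adjusted p = 0.003), a call lost without aFGF replicate 1, and FGFR3 one of 0.31 (SE 0.08, adjusted p = 0.013), a call lost without any one of the arrays with aFGF. FGFR1 stood at -0.11 (SE 0.05, adjusted p = 0.13) and passed the threshold without either DMSO array.

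AZD4547 changed 4894 genes, 2964 upward and 1930 downward, with 149 rises and 116 falls of at least 2-fold and 6563 genes at an unadjusted p under 0.05. Without aFGF replicate 1 or 2 the counts were 3047 and 3046, and without AZD4547 replicate 1 the count was 3236, again with the lone culture assumed to vary like the other groups.

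Genes that aFGF raised or lowered were compared with those that AZD4547 moved the other way. Of 1128 genes that rose with aFGF, 972 (86.2%) fell with AZD4547, where independent lists would share 114.3. Of 1851 that fell, 1676 (90.5%) rose, where independent lists would share 288.1. These make 2648 opposed calls, and 0 genes were called in the same direction in both comparisons, where independent lists would share 175.6 upward and 187.6 downward. Both comparisons use the aFGF arrays. Simulated arrays with no effect gave 0 opposed calls on average over 100 draws, but then only 0.06 and 0.03 genes were called at all, so this count gives no reference for sharing where many genes are called. They gave a correlation of fold changes across genes of -0.4998, against -0.855 observed. The covariance was -0.0721 against -0.00835 simulated, a difference of -0.0638. With 2 aFGF arrays the group cannot be split so that each part keeps 2, and part of the excess of opposed calls over independent lists may come from the shared arrays, whose share the difference of covariances already leaves out. Without aFGF replicate 1 or 2 the opposed calls numbered 1167 and 1069, and without the intensity trend 1377.

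**Figure D2:**
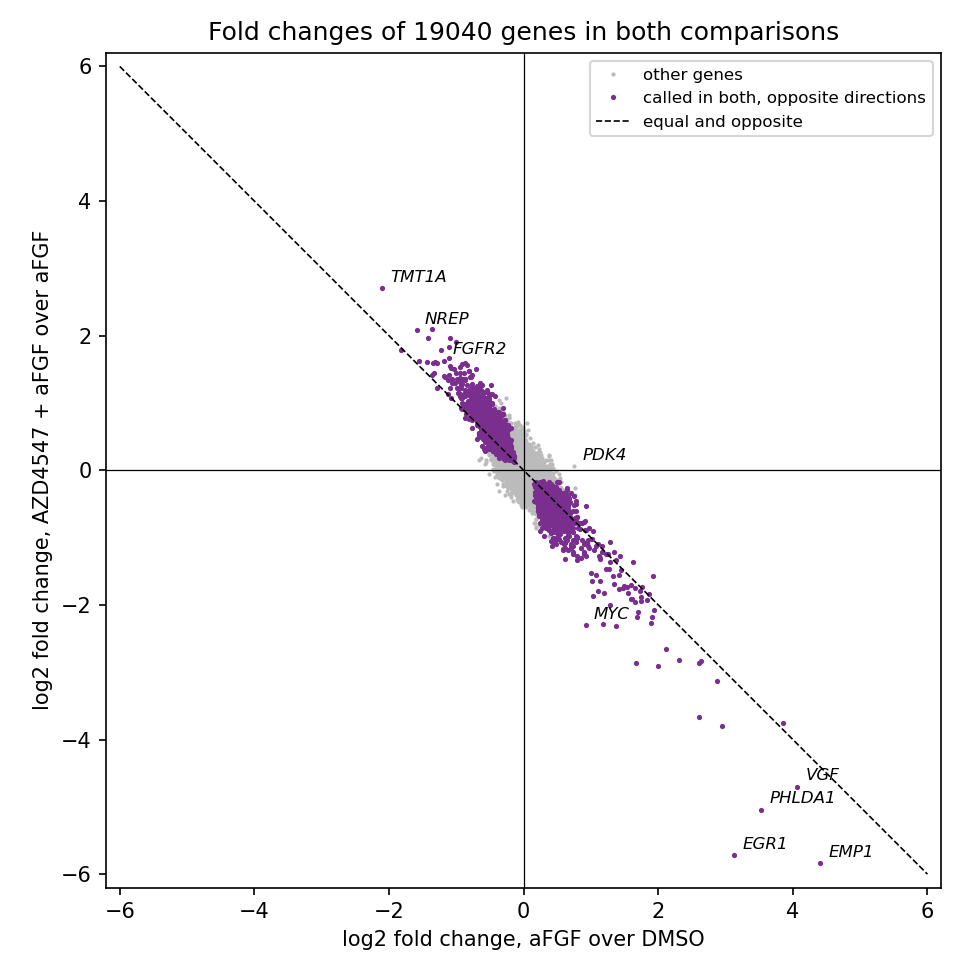
Log2 fold change of each of 19040 genes with aFGF over DMSO (horizontal axis) against AZD4547 with aFGF over aFGF (vertical axis), with a point per gene and a dashed line for equal and opposite changes. The 2648 genes called in both comparisons all lie in the quadrants of opposite sign, EMP1 at 4.41 and -5.84 and TMT1A at -2.11 and 2.71, and PDK4 lies at 0.75 and 0.06.

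The third comparison set cells given aFGF and AZD4547 against cells given neither, and so asked where expression with the inhibitor lay relative to unstimulated cells. EGR1 was 6.02-fold below its DMSO level (log2 -2.59, SE 0.06, limma adjusted p = 2.7e-09). PHLDA1 (-1.50, SE 0.08), EMP1 (-1.43, SE 0.09), MYC (-1.38, SE 0.08), SERPINB8 (-1.19, SE 0.07), the AP-1 subunit FOSL1 (-1.09, SE 0.09) and GDF15 (-1.05, SE 0.09) also lay below DMSO. These 7 were the genes at least 2-fold below it, and 0 genes were at least 2-fold above. The level of EMP1 with AZD4547 was dim, as above, and so were the DMSO levels of the rises below for DDX60, MAP2K6, CCDC80, PLCXD2 and ABAT (2.28 to 2.58). MAP3K14 followed at -0.94 (SE 0.10), a call lost without AZD4547 replicate 2. The largest rises were PPP1R3C (0.89, SE 0.12), ATP2B4 (0.88, SE 0.11), PDK4 (0.81, SE 0.07), DDX60 (0.80, SE 0.12), MAP2K6 (0.79, SE 0.13), CCDC80 (0.78, SE 0.12), PLCXD2 (0.76, SE 0.16) and ABAT (0.74, SE 0.16). Apart from PDK4, whose product restrains pyruvate oxidation, each of these 8 rises lost its call without AZD4547 replicate 1 and without AZD4547 replicate 2. Without the intensity trend 0 genes were called above DMSO, so the calls of all 8 rises, PDK4 included, were lost. Those of NOP16, IER2 and SLC7A5, below DMSO, were lost as well. Of 47 named calls in this comparison, 11 held whichever array was left out, against 54 of 73 for aFGF and 68 of 77 for AZD4547.

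Ribosome biogenesis and MYC target genes were lower than in DMSO in 26 of 34 cases and higher in 0 (33 and 0 adjusted over the list alone, median log2 -0.38, camera adjusted p = 1.3e-35, adjusted p = 0.012 with an estimated correlation), among them NOP16 (-0.71, SE 0.07). ERK pathway output genes were lower in 12 and higher in 2 of 24 cases (12 and 2 adjusted over the list alone, camera adjusted p = 4.3e-10, adjusted p = 0.038 with an estimated correlation). Immediate early genes were lower in 5 and higher in 0 of 20 cases (6 and 0 adjusted over the list alone, camera adjusted p = 1.1e-05, adjusted p = 0.074 with an estimated correlation), with IER2 at -0.60 (SE 0.06). ATF4 and unfolded protein response genes were lower in 3 and higher in 0 of 25 cases (7 and 0 adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.18 with an estimated correlation), and the list call was lost without AZD4547 replicate 2 (adjusted p = 0.16). The amino acid transporter SLC7A5 led this list at -0.71 (SE 0.07).

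G2/M and mitosis genes were above DMSO in 12 and below it in 0 of 33 cases (20 and 0 adjusted over the list alone, camera adjusted p = 4.8e-14, adjusted p = 0.038 with an estimated correlation), with ASPM at 0.43 (SE 0.06) and the centromeric histone CENPA at 0.42 (SE 0.06). CDK inhibitors and quiescence genes were above it in 5 of 28 cases and below it in 0 (9 and 1 adjusted over the list alone, camera adjusted p = 5.8e-07, adjusted p = 0.041 with an estimated correlation), with CCNG2 at 0.73 (SE 0.08) and BTG2 at 0.54 (SE 0.09). The CCNG2 call was lost without AZD4547 replicate 1, and those of ASPM, CENPA and BTG2 without either AZD4547 array. Without the intensity trend the calls of ASPM, CENPA, CCNG2 and BTG2 were lost too, as was that of every other gene above DMSO. The lists themselves were not tested without the trend. Cholesterol synthesis genes were higher in 3 of 24 cases (5 adjusted over the list alone, camera adjusted p = 6.1e-05, adjusted p = 0.074 with an estimated correlation). Glycolysis genes were higher in 2 of 20 cases (2 adjusted over the list alone, camera adjusted p = 0.0065, adjusted p = 0.12 with an estimated correlation). Interferon genes were higher in 2 of 30 cases (5 adjusted over the list alone, camera adjusted p = 0.0036, adjusted p = 0.17 with an estimated correlation), and 0 genes of these lists were lower, also when adjusted over the list alone. In the G1/S and replication list 0 of 38 genes were called, also when adjusted over the list alone, while the list as a whole was shifted upward (median log2 0.06, camera adjusted p = 0.011, adjusted p = 0.15 with an estimated correlation), a call lost without AZD4547 replicate 1 (adjusted p = 0.095) and without dim genes (0.072). FGFR2 lay 0.44 (SE 0.05, adjusted p = 0.0017) and FGFR3 0.33 (SE 0.08, adjusted p = 0.041) above DMSO, while FGFR1 lay below it (log2 -0.21, SE 0.05, adjusted p = 0.028) and FGFR4 had a log2 fold change of -0.09 (SE 0.08, adjusted p = 0.60). These 3 calls were lost without either AZD4547 array and without the intensity trend. Those of FGFR1 and FGFR3 were also lost without either aFGF array and with the mean of a gene's probe sets, that of FGFR3 without DMSO replicate 1, and that of FGFR1 after median centring (adjusted p = 0.052). A fit of only the groups compared ended both as well.

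This comparison called 892 genes, 434 above and 458 below DMSO, with 3511 at an unadjusted p under 0.05. The aFGF arrays enter this comparison only through the estimate of spread. The count fell when any single aFGF or AZD4547 array was left out, so it depended on each of these arrays. Each removal also leaves fewer arrays for the estimate of spread, so the removals cannot show whether a single array drove the count. It was 29 without AZD4547 replicate 2, 43 without AZD4547 replicate 1, 225 and 220 without aFGF replicate 1 or 2, and 1556 without DMSO replicate 2, with the lone culture of a group assumed to vary like the other groups. It was 10 without the intensity trend, 0 above and 10 below DMSO, and 217 when the aFGF arrays were left out of the fit. In the authors' deposited table, 4305 of 49293 probe sets had a p under 0.05 for this pair of groups. That p has no stated adjustment and counts probe sets, so the number is not comparable with the genes called here.

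**Figure D3:**
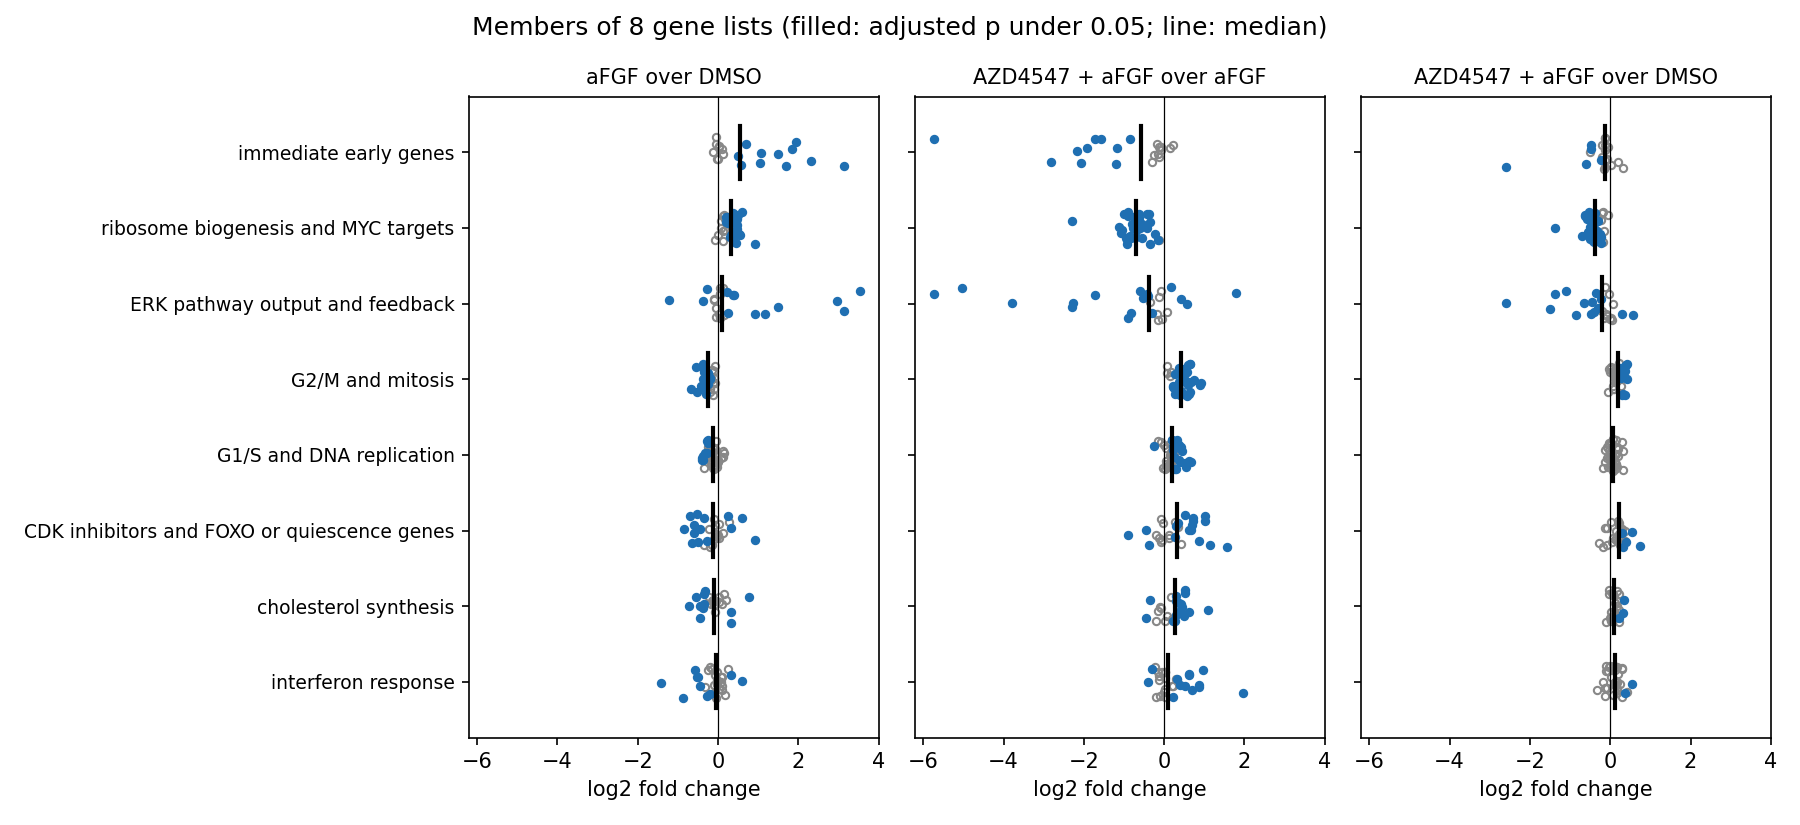
Log2 fold change (horizontal axis) of the members of 8 gene lists (vertical axis) in each of the 3 comparisons, with a point per gene, filled where the limma adjusted p was under 0.05, and a line at each list's median. The median of the ribosome biogenesis and MYC list stood at 0.33, -0.70 and -0.38, and that of the G2/M and mitosis list at -0.24, 0.42 and 0.20.

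The remaining lists gave no camera call in any comparison, apart from the ATF4 list against DMSO. ATF4 and unfolded protein response genes moved both ways, with 6 rises and 4 falls of 25 for aFGF (7 and 7 adjusted over the list alone) and 5 rises and 9 falls for AZD4547 (5 and 10 adjusted over the list alone). CEBPB rose by 0.80 (SE 0.06) and DDIT3, a stress-induced factor, by 0.72 (SE 0.12, from a dim 2.69) with aFGF, and the stress sensor SESN2 rose by 0.79 (SE 0.09) with AZD4547. With aFGF, 5 of 31 epithelial, mesenchymal and matrix genes rose and 2 fell (5 and 2 adjusted over the list alone), and with AZD4547 2 rose and 6 fell (3 and 6 adjusted over the list alone). THBS1 (1.73, SE 0.09) rose with aFGF, while fibronectin, FN1, fell (-0.82, SE 0.10). The median of this list was -0.01 and its mean 0.19 with aFGF. The fry test, which does not compare a list with other genes, called this list upward with aFGF (adjusted p = 0.001) and downward with AZD4547 (adjusted p = 0.00034). It also called glycolysis downward with aFGF (0.026), and with AZD4547 the ATF4 list downward (0.0087) and lysosome genes upward (0.022). Against DMSO it called cytokines downward (0.046) and did not call interferon genes (0.053). Of the cytokine genes, 0 were called against DMSO. The median mean log2 level was 1.04 in the cytokine list and 2.04 in the epithelial, mesenchymal and matrix list. Both lie below the array medians, so these fry calls rest largely on levels not shown to be above background. In the BCL2 family the proapoptotic BAD fell by 0.64 (SE 0.07) with aFGF and rose by 0.95 (SE 0.07) with AZD4547, with 1 rise and 2 falls of 16 for aFGF (1 and 3 adjusted over the list alone) and 2 and 2 for AZD4547 (2 and 2 adjusted over the list alone). Lysosome and autophagy genes had 3 rises and 5 falls of 24 for aFGF (4 and 5 adjusted over the list alone) and 8 rises and 1 fall for AZD4547 (10 and 2 adjusted over the list alone). Cytokine genes had 0 rises and 1 fall of 18 for aFGF (0 and 0 adjusted over the list alone), and endometrial lineage genes 1 rise and 1 fall of 23 (1 and 1 adjusted over the list alone). For AZD4547 these counts were 1 and 1 (1 and 0 adjusted over the list alone) and 4 and 1 (4 and 1 adjusted over the list alone). With AZD4547, FGF receptor list genes had 5 rises and 5 falls (6 and 6 adjusted over the list alone) and other receptor tyrosine kinases 4 rises and 1 fall (4 and 1 adjusted over the list alone).

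Markers of other cell types showed no list call in any comparison. Median mean log2 intensities were 1.82 for 8 fibroblast markers, 1.80 for 7 endothelial, 1.31 for 8 leukocyte and 2.5 for 5 smooth muscle markers, all below the array medians of log2 intensity, which lay between 2.843 and 2.893. COL1A2, a fibroblast marker, stood at 9.56 in DMSO. It was 0.19 (SE 0.06, adjusted p = 0.046) higher with aFGF, while COL3A1, of the same list, was lower (log2 -0.55, SE 0.11) and rose by 0.77 (SE 0.11) with AZD4547. Both collagens were named after their values were seen.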

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

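Of 206 named gene values, 197 were called, with 0 sign changes of a called value in the settings that gave one. Settings that leave the group means as they are, such as the replicate block, the robust prior or no trend, cannot change a sign. Without the intensity trend 56 of the calls were lost, and with probe set means 23. With only the groups compared 21 were lost and 1 was gained. Without dim genes 196 had a value and without _x_at probe sets 201, and every probe set and the fold minimum were not run for them. Array weights and the removal of _x_at probe sets were chosen after seeing the data. Genes called for aFGF, for AZD4547 and against DMSO, and opposed calls, stayed within 1.5 times of 2979, 4894, 892 and 2648 with a robust prior, without dim genes, after renewed quantile normalization or median centring, with probe set means, with array weights and without _x_at probe sets. Similar counts did not mean the same genes. Among these settings the fewest calls were kept with probe set means. There 2205 of the 2979 genes stayed called for aFGF, 4021 of the 4894 for AZD4547 and 560 of the 892 against DMSO. Without the intensity trend, 1489 genes were called for aFGF, 10 against DMSO (0 above and 10 below) and 1377 opposed. The excess of falls with aFGF was smaller than in the first fits after median centring (1251 up, 1482 down) and with probe set means (1169 up, 1604 down). So was the excess of rises with AZD4547 (2624 up and 2153 down after centring, 2699 up and 2113 down with probe set means). A fit of only the groups compared called 217 against DMSO. A fold minimum of 2 left 101, 265 and 7 genes. Testing every probe set called 5542 probe sets for aFGF and 9957 for AZD4547, since 47340 were tested. The lists were not tested without the trend, with a robust prior, with array weights or with only the groups compared. Every camera test kept the intensity trend. With an estimated correlation, 3, 4 and 4 lists were called for aFGF, AZD4547 and against DMSO, instead of 8, 9 and 10, and with fry 10, 12 and 10. For aFGF, 6 lists were called without dim genes, 6 without _x_at probe sets and 7 after median centring, and against DMSO 9 without dim genes. Leaving out each array in turn, with a lone culture assumed to vary like the other groups, gave 1147 to 3448 genes for aFGF, 3046 to 5667 for AZD4547, 29 to 1556 against DMSO and 1069 to 2823 opposed calls, with 5 to 7, 9 (each time) and 9 to 10 lists called. Unless the setting itself has fewer arrays or more probe sets, the cause was not tested. The replicate numbers were not taken as pairs: the deviations of same-numbered arrays correlated at 0.001, 0.058 and -0.04 (0.061, 0.102 and -0.073 among brighter probe sets), and the labels do not say whether a number marks a shared batch. With a replicate block the counts were 3302, 5161, 1201 and 2874, with 8, 9 and 10 lists. The deposited values carry no detection calls, so the signal over background behind a dim gene is unknown.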

Other observations

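The Gene Ontology terms, the tests of the mitosis genes against random lists, the share over all brighter genes, the simulated count of genes called alike, and the counts of genes moved back and of called genes among those picked were chosen after the results were seen. The other tests were set before their values were seen. Over 823 biological-process terms of 15 to 300 genes in the deposited annotation, camera called 4 upward and 6 downward for aFGF and 15 upward and 9 downward for AZD4547. With an estimated correlation 0 terms were called (adjusted p = 0.91 and 0.81). That test uses the few residual degrees of freedom, so hardly any of so many terms could pass. The loss is therefore not shown to come from correlation between genes. For the ribosome biogenesis and MYC list with AZD4547, the estimated correlation was -0.01, yet the camera adjusted p went from 1e-28 to 0.016. The terms are called under the preset correlation only. Genes of mitochondrial electron transport from NADH to ubiquinone, the entry step of the respiratory chain, fell with aFGF in 13 of 36 cases and rose in 0 (median log2 -0.14, camera adjusted p = 0.0027). With AZD4547, 17 of these 36 rose and 1 fell (median log2 0.20, camera adjusted p = 0.00039). Purine nucleotide synthesis genes fell with AZD4547 in 12 of 16 cases and rose in 0 (median log2 -0.37, camera adjusted p = 8.7e-05), and 6 of the 16 lay below DMSO. Genes of tRNA processing fell in 35 and rose in 8 of 75 cases with AZD4547 (median log2 -0.21, camera adjusted p = 0.001).

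Mitosis genes were lower with aFGF, a growth factor, and higher with the inhibitor of its receptors. A trend of fold change with brightness, left by the authors' normalization, would move lists of equal brightness alike. The median of the 33 genes lay at percentile 0 of 10000 random lists matched on mean expression for aFGF (-0.24, against -0.11 to 0.06 for the central 95% of lists) and at percentile 100 for AZD4547 (0.42, against -0.09 to 0.15), which argues against that trend as the cause. A single deviating array is argued against as well, since leaving out any 1 array of the groups compared kept at least 91.9% of the median. An array outside the groups compared cannot move that median. The fall and the rise share the aFGF arrays, so they are not independent. A change in the share of cells in mitosis under each treatment is a candidate explanation that stays open and was not tested, as no cell counts or cycle phases were used here.

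PDK4 rose with aFGF by 0.75 and lay 0.81 above DMSO with AZD4547, as 1 of 42 genes (30 higher, 12 lower) called in the same direction with aFGF and with AZD4547 and aFGF, each over DMSO. Independent lists would share 25.7 higher and 44.5 lower genes, but both comparisons use the DMSO arrays, and simulated arrays with no effect gave 0.01 such genes on average, as hardly any gene was then called, and a correlation of fold changes of 0.5014, against -0.1812 observed (covariance 0.008385 against -0.00806, a difference of -0.01645), so part of the overlap may come from the shared arrays. Of 42 genes picked as shifted alike in the replicate 1 arrays, 83.3% kept their direction in the replicate 2 arrays, and 88.1% the other way round. At least 80% had been set beforehand to count against errors of the DMSO arrays, but that bound was wrong for the called genes, as only 16 and 11 of the picked genes were among them and 64.5% of all brighter genes kept their direction too, so such errors stay open. AZD4547 moved 12 of the 42 back from their level with aFGF and 30 were not called in that comparison, so partial reversal of an aFGF effect stays open for some, and 23 calls remained without DMSO replicate 1 and 38 without DMSO replicate 2.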
